A study of Mus musculus with 15 samples.

How the data were processed

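RNA from the heads of 15 mouse embryos at embryonic day 9.5 (18 to 20 somites) was measured on Illumina bead arrays of 1 colour, with 1 head per array. Per the labels, the embryos were of mixed laboratory strain descent and fell into 4 genotype groups. Control heads (n = 3) had a floxed and a wild-type Twist1 allele and no Cre. Het heads (n = 4) had a floxed and a deleted Twist1 allele and no Cre. CM-Het heads (n = 4) had a floxed and a wild-type allele and Cre from the Mesp1 locus, which is active in early mesoderm. CM-CKO heads (n = 4) had a floxed and a deleted allele and Mesp1-Cre, so that the Cre lineage, including cranial mesoderm, would lose both copies and all other cells would keep 1. RNA was extracted on micro columns and labelled at a service facility. The arrays lay on 3 slides: slide 1 held Het 1 and CM-CKO 1 to 3, slide 2 held CM-Het 1 and 2, Het 2 and 3 and Control 1, and slide 3 held CM-Het 3 and 4, Het 4, Control 2 and 3 and CM-CKO 4.

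The deposited signals were intensity values, 1 bead summary per probe and array, neither normalized nor background-subtracted, and the software that made them is not given in the sources used here. Beside each signal column, per the file headers, the deposited table held a detection p-value for each probe, which is the share of negative control beads above the signal. The authors' value table held log2 signals. Quantile normalization of the deposited signals without background correction gave the same log2 value within 0.02 for 42477 of 45281 probes, and the other 2804 rows equalled another probe within 10 rows. Both probes had a gene name in 2544 of these rows, and in all 2544 the gene was the same. Which of the tables has the right probe for these rows is not known, and this bears on the calls that ended or turned in the authors' value table.

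The deposited detection p-values were not in the row order of the signals: between 74.4% and 75.6% of the entries of an array were out of place by over 0.05. Because a detection p falls as the signal rises, the p-values of 14 arrays were re-attached to the signals by rank within each array. The detection column of Het 1 held the same numbers as its column of the value table (largest difference 0), and its p-values were taken as the average by rank over the other 14 arrays. The step between p-values implied 936 negative control beads.

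Signals were background-corrected by the normexp model with the mean and spread of negative controls inferred from the detection p-values (limma, function nec, offset 16), quantile-normalized and put on a log2 scale. A probe was kept where its detection p was under 0.05 on at least 3 arrays, which left 21869 probes. Gene names came from the probe table given for the series: 34885 probes had 1 gene name, 18 had several and 10378 had none, and 34807 had an Entrez ID in the RefSeq table (mouse GRCm38.p6), through which 0 symbols were updated. Each gene was represented by its brightest kept probe, which gave 11625 genes. Of these, 4669 had more than 1 kept probe. Probes with no gene name were fitted apart and are counted only in the closing section. Gene positions were taken from the RefSeq table. Probe sequences were not used here, so the place of a probe within its gene is not known.

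The deposited mean signal per array ran from 341.0 to 434.4, and 19204 to 19793 probes were detected per array at detection p under 0.05. The signal at that threshold was 106 to 121. The number of embryos and the signal over background limit the precision of every value. The p-values of genes and the permutation tests measure the spread between these embryos, whereas camera sets the genes of a list against all others and Fisher's exact tests count genes. A gene that was not detected on any array of a group counted as below background there. Its change is given as a fold of at least the ratio to the signal at the detection threshold. A gene detected on only some arrays of a group has an ordinary fold change, even where its group mean lay below that threshold.

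The 4 groups were fitted together in 1 linear model with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes at default settings), with genotype as the only factor. The comparisons were CM-CKO with Control, Het and CM-Het, Het with Control, CM-Het with Control, and the interaction, which is the CM-CKO minus Het change minus the CM-Het minus Control change. A gene counted as changed where its Benjamini-Hochberg adjusted p, over all genes of a comparison, was under 0.05. Errors of log2 fold changes are standard errors (SE) of the fit, and errors of group means are standard deviations (SD). Twist1 levels were also compared by exact permutation tests over all splits of the arrays of 2 groups. Figures were drawn with matplotlib 3.10.9.

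The design, the alternatives, the rule for named genes and 31 gene lists were fixed before the data were examined. The lists were mesenchyme and EMT transcription factors, mesenchyme markers, extracellular matrix, integrins and adhesion receptors, epithelial genes, neural crest and arch, head muscle mesoderm, endothelial, erythroid, macrophage and hematopoietic, cardiac, trunk Hox and somite, hindbrain Hox, forebrain and midbrain progenitor, neuron differentiation, ear and lens placode, pharyngeal endoderm and ectoderm, notochord and floor plate, FGF targets, BMP and TGF-beta targets, Wnt targets, hedgehog targets, retinoic acid, Notch, suture and craniosynostosis, ephrin and semaphorin guidance, p53 and apoptosis, hypoxia and glycolysis, cell cycle, stress and immediate early, and sex-linked genes. They were tested with camera (preset correlation between genes 0.01) where at least 5 members were measured, which was so for 30 lists, and adjusted over the lists within a comparison. Camera with a correlation estimated per list was run beside it, as was fry. Counts of changed genes in a list use the adjustment over all genes unless they are said to be adjusted over the list alone. A list score is the mean over the list of log2 differences from the Control mean.

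Named genes followed a fixed rule. Twist1, Twist2, Mesp1 and Mesp2 were always given where measured. In each CM-CKO comparison the 10 higher and 10 lower changed genes with the largest log2 fold change were eligible, and 5 and 5 in the other comparisons. Where fewer than 3 genes passed, the 5 with the smallest p were taken as values that did not pass. Sex-linked genes and predicted or clone names were skipped. For each list in CM-CKO against Control and against Het, up to 4 changed members were named, or up to 2 where none changed. Other list members that the text names were chosen after their values were seen.

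The alternatives tried were no background correction, median scaling instead of quantile normalization, the authors' value table, no detection filter, a stricter detection filter, the mean of all kept probes of a gene, slide as a fixed or random block, replicate number as a block with and without slide, array weights, trended and robust empirical Bayes, a fit of only the groups compared, and leaving out each array in turn. The Xist level and the erythroid list mean as covariates were added after the data had been seen. List tests were not run with these covariates. A list median with the erythroid covariate therefore has no error or test, and its change of sign is not a tested reversal. Chance groupings were counted by repeating each comparison over all splits of its arrays, or over 100 splits for the interaction. Nearness to Twist1 and Mesp1 was tested by Fisher's exact test within 10 Mb, and within 5 and 20 Mb as alternatives. The overlap of changed genes between comparisons that share arrays was left out because shared arrays produce overlap by chance.

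The steps were tested on simulated data with the spread and group sizes of these arrays. With no change put in, 0 or 1 of 11625 genes were called per comparison. A log2 change of 1 was recovered for 84.1% to 94.3% of genes and a change of 0.5 for 32.8% to 49.3%. False calls made up 3.36% to 6.55% of the calls. A shift of 0.3 put into the cell cycle list was recovered by camera (adjusted p = 1.15e-25) with 0 of the other lists called. Genes were drawn independently of each other and with the same spread in every group. The simulation therefore cannot show how often the list tests call falsely on real arrays, where genes of a list vary together. Nor can it show how often genes are called falsely where 1 group varies more than the others. The erythroid score, for example, had an SD of 0.92 in CM-CKO heads and of 0.14 to 0.21 in the other groups.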

Results

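Gene expression was measured in whole heads of mouse embryos at embryonic day 9.5, 1 head per array, to find genes that depend on the transcription factor TWIST1 in the cranial mesoderm. There were 3 Control heads, 4 Het heads, 4 CM-Het heads and 4 CM-CKO heads. A head at this stage holds cranial mesoderm together with neural crest, brain, surface ectoderm, pharynx, vessels and blood, so each value is an average over all of these. Arrays correlated with each other at r = 0.964 to 0.994 over the tested genes. The first principal component carried 37.3% of the variance and set the CM-CKO heads (scores 9.58 to 45.2) apart from all other heads (scores −11.1 to −7.57). The second carried 13.5% and set the arrays of slide 1 (Het 1 and CM-CKO 1 to 3, scores −20.4 to −5.90) apart from all others (−3.19 to 19.6).

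Twist1 was read by 1 probe (gene on chromosome 12, 33957671 to 33959831, GRCm38.p6), which was detected on all 15 arrays. Its log2 level was 9.92 ± 0.04 (SD, n = 3) in Control, 9.91 ± 0.14 (SD, n = 4) in CM-Het, 8.97 ± 0.32 (SD, n = 4) in Het and 9.16 ± 0.17 (SD, n = 4) in CM-CKO heads. The Het level was 51.6% of Control (log2 −0.95, exact permutation p = 0.0286, the smallest that 35 splits allow). In CM-CKO heads the level was 59.0% of Control (log2 −0.76, exact permutation p = 0.0286) and 59.4% of CM-Het (log2 −0.75, exact permutation p = 0.0286). Adjusted over the 6 pairs of groups each of these exact permutation tests gave adjusted p = 0.0429. CM-CKO and Het heads, which share the floxed and deleted Twist1 alleles, had no difference that passed (114%, log2 0.19, exact permutation p = 0.286), and CM-Het heads held 99.3% of the Control level (exact permutation p = 0.914). In the fit over all genes the CM-CKO decrease had adjusted p = 0.0063 against Control and 0.0034 against CM-Het, and with slide as a block the changes were −0.51 (adjusted p = 0.0663) and −0.52 (adjusted p = 0.0510). Within slide 3, CM-CKO 4 lay at −0.61 from Control and −0.59 from CM-Het. It was the only CM-CKO head on that slide, so every CM-CKO value within slide 3 rests on 1 array. The Het level shows that the signal was lower where 1 allele was deleted in all cells. Where the probe lies relative to the deleted part of Twist1 is not given in the sources used here. Each head also mixes the Cre lineage with other cells. The level therefore does not measure how completely Cre removed the gene. Mesp1 (chromosome 7, 79792241 to 79793590) and Mesp2 each had 1 probe, detected on 0 arrays. The related gene Twist2 fell by 0.59 ± 0.14 (SE) in CM-CKO against Control (adjusted p = 0.0223) and by 0.51 ± 0.13 against Het (adjusted p = 0.0273), and was not changed against CM-Het (−0.19, adjusted p = 0.394). Both Twist2 calls ended with median scaling.

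**Figure D1:**
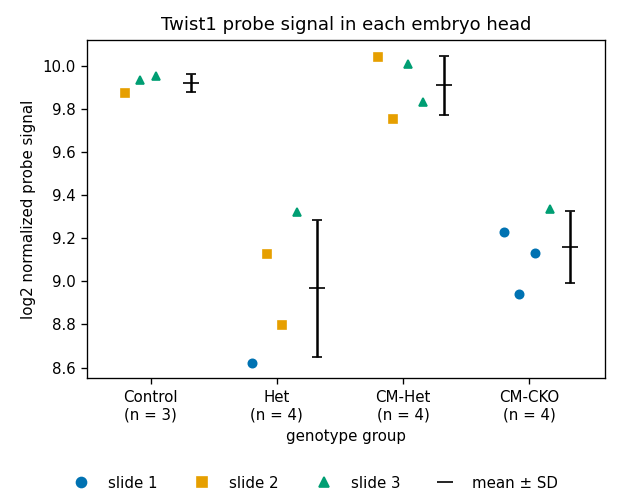
Log2 normalized signal of the Twist1 probe (vertical axis) in each embryo head, by genotype group, with point shape and colour for the slide and black bars for the group mean ± SD. Control and CM-Het heads averaged 9.92 and 9.91, and Het and CM-CKO heads averaged 8.97 and 9.16.

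The first comparison set heads bred to lose both copies of Twist1 in the mesoderm lineage and to keep 1 copy elsewhere (CM-CKO, n = 4) against heads with 2 copies (Control, n = 3). The extent of that loss was not measured. The largest rise was in Chac1, a glutathione-degrading enzyme of the amino acid stress response, at 3.53 ± 0.24 (SE) on the log2 scale or 11.6-fold (adjusted p = 5.27e-07). Trib3, another gene of that response, rose by 2.91 ± 0.37 (adjusted p = 0.000253). The largest fall was in Klf2, a flow-responsive endothelial transcription factor, which fell by 1.77 ± 0.16 (adjusted p = 9.37e-06). The matrix proteoglycan Lum, made by mesenchyme, fell by 1.41 ± 0.10 (adjusted p = 6.38e-07), and the actin-binding gene Tagln rose by 1.60 ± 0.12 (adjusted p = 1.31e-06).

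In all, 841 of 11625 genes changed, 460 higher and 381 lower, with 180 higher and 21 lower by at least 2-fold and a median size of 0.65 among the changed genes. A slide block gave 941 genes, but the replicate block together with slide gave 31 and the erythroid list mean as a covariate, chosen after the data were seen, gave 166. Within slide 3 all 841 genes kept their sign, although those arrays had also served for the calls. Median scaling in place of quantile normalization gave 434 genes, of which 77.4% were higher, against 54.7% of the 841. The count was 386, 385 and 409 without Control 1, 2 and 3 and 397 without CM-CKO 2. A fit of only these 7 arrays gave 272 genes.

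Among the 10 largest rises were genes of red blood cells. The membrane protein Kel rose by 2.95 ± 0.48 (adjusted p = 0.002), the heme synthesis enzyme Alas2 by 2.94 ± 0.50 (adjusted p = 0.00247), the spectrin gene Sptb by 2.77 ± 0.41 (adjusted p = 0.000944, with 1 of its 2 probes in that direction), the anion exchanger Slc4a1 by 2.75 ± 0.38 (adjusted p = 0.000489) and the amino acid transporter Slc38a5 by 2.71 ± 0.51 (adjusted p = 0.00493). With the erythroid list mean as a covariate these genes moved by 0.63, 0.55, 0.84, 0.95 and 0.18, and only Slc4a1 passed (adjusted p = 0.0471). The platelet factor Pf4 rose by 3.35 ± 0.42 (adjusted p = 0.000216) and the circadian and hypoxia-responsive repressor Bhlhe40 by 2.96 ± 0.23 (adjusted p = 1.31e-06). The heat shock gene Hspa1a lay below background in Control and was at least 6.72-fold higher in CM-CKO heads (adjusted p = 0.0415), with an SD of 2.52 among them. Its call ended without background correction, and with the erythroid covariate its fitted difference was −0.74 and did not pass. Blocking by slide put Chac1 at 3.74, Bhlhe40 at 2.53, Pf4 at 3.52 and Klf2 at −1.56, and within slide 3 they were at 4.02, 2.51, 3.43 and −1.53.

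The other large falls were led by genes of vessels. The arterial connexin Gja4 fell by 1.52 ± 0.17 (adjusted p = 6.04e-05), the apelin receptor Aplnr by 1.48 ± 0.17 (adjusted p = 8.19e-05) and the adhesion molecule Vcam1 by 1.35 ± 0.23 (adjusted p = 0.0026). The heme protein Cygb, found in stromal and mural cells, fell by 1.48 ± 0.14 (adjusted p = 1.41e-05), and the methyltransferase Inmt fell by 1.22 ± 0.23 (adjusted p = 0.00534). Fam162b was below background in CM-CKO heads and at least 2.46-fold lower (adjusted p = 4.87e-05). The acyltransferase Mogat2 fell by 1.25 ± 0.13 (adjusted p = 2.83e-05) and the carbonyl reductase Cbr3 by 1.24 ± 0.14 (adjusted p = 7.56e-05), and the Cbr3 call ended in the authors' value table.

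**Figure D2:**
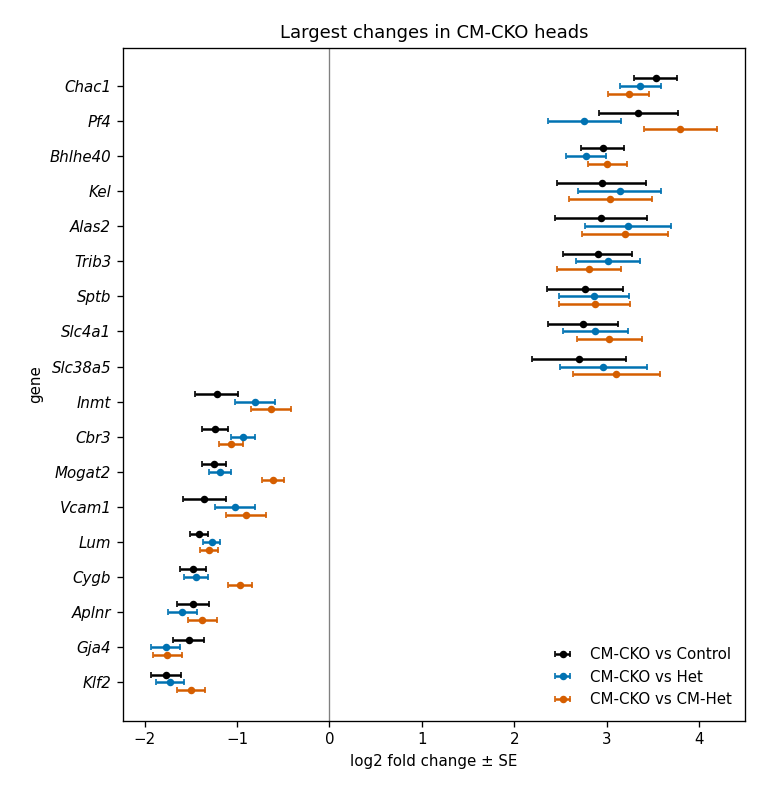
Log2 fold change ± SE (horizontal axis) of the genes with the largest rises and falls in CM-CKO against Control heads, leaving out Hspa1a and Fam162b, whose level was below background in 1 group. Each gene is drawn for CM-CKO (n = 4) against Control (n = 3), Het (n = 4) and CM-Het (n = 4), and every gene keeps its direction in the 3 comparisons, with Chac1 at 3.53, 3.37 and 3.24. The comparisons share the CM-CKO arrays and the genes were chosen by the first, so the shared direction is no independent support.

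Genes induced by low oxygen and of glycolysis formed the clearest group. Of 31 measured list members 23 rose and 0 fell, and the median was 0.70 (adjusted p = 6.75e-28, and adjusted p = 0.000237 with an estimated correlation). Stc2 rose by 2.19 ± 0.17 (adjusted p = 1.24e-06), Ddit4 by 2.10 ± 0.17 (adjusted p = 1.41e-06), Ankrd37 by 1.59 ± 0.15 (adjusted p = 9.37e-06) and Plod2 by 1.00 ± 0.11 (adjusted p = 3.48e-05). The angiogenic factor Vegfa rose by 1.09 (adjusted p = 0.002), while the glycolytic enzymes Gapdh (−0.05) and Ldha (−0.05) did not change. With slide as a block the list median was 0.69, and within slide 3 the mean difference was 0.72. Cell cycle genes, of which 0 of 29 rose and only the nucleotide reductase Rrm2 fell (by 0.54 ± 0.11, adjusted p = 0.0079), had a median of −0.05 (adjusted p = 0.426).

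Red blood cell genes rose by a median of 1.88, with 14 of 21 higher and 0 lower (adjusted p = 8.46e-15, and adjusted p = 0.261 with an estimated correlation). Beyond Slc4a1, Kel and Alas2, Mgst3 rose by 2.38 ± 0.40 (adjusted p = 0.00221) and the erythroid regulator Klf1 by 2.55 (adjusted p = 0.0064). The embryonic globins Hbb-bh1 (−0.04) and Hbb-y (0.12) did not change, but their Control levels (13.67 and 13.68) were near the highest of any gene on any array (14.05). In the macrophage and hematopoietic list 6 of 11 genes rose, with a median of 0.65 (adjusted p = 1.28e-05, and adjusted p = 0.261 with an estimated correlation). Besides Pf4, Itga2b rose by 1.83 ± 0.37 (adjusted p = 0.00741), F2rl2 by 1.72 ± 0.31 (adjusted p = 0.00354) and Treml1 by 1.72 ± 0.35 (adjusted p = 0.00858), while the macrophage genes Aif1 (−0.15) and Mrc1 (0.03) did not change. In the fit of only these arrays the Slc38a5, F2rl2 and Treml1 calls ended. The slide block medians were 2.56 for red blood cell and 0.64 for macrophage and hematopoietic genes, and within slide 3 the mean differences were 2.71 and 1.18.

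Stress and immediate early genes rose by a median of 0.44, with 10 of 24 higher and 0 lower (adjusted p = 6.75e-07, and adjusted p = 0.0714 with an estimated correlation). Ier3 rose by 1.92 ± 0.20 (adjusted p = 2.83e-05), Egr1 by 1.74 ± 0.19 (adjusted p = 4.88e-05), Ccn1 by 1.38 ± 0.20 (adjusted p = 0.000743) and Atf3 by 0.81 ± 0.19 (adjusted p = 0.0214). The list stood at 0.62 with slide as a block and at 0.91 within slide 3. With the erythroid covariate its median was 0.08. In the p53 and apoptosis list, at a median of 0.09 (adjusted p = 0.215), 3 genes rose and 2 fell, among them the cell cycle inhibitor Cdkn1a, which rose by 1.00 ± 0.17 (adjusted p = 0.00252), and Sesn2, at 0.86 ± 0.16 (adjusted p = 0.00419), which lost its call in the authors' value table.

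Endothelial genes fell by a median of 0.34, with 10 of 29 lower and 1 higher (adjusted p = 2.13e-06, and adjusted p = 0.261 with an estimated correlation). Adjusted over the list alone 17 changed. The arterial connexin Gja5 fell by 1.20 ± 0.16 (adjusted p = 0.000296) and Sox7 by 0.92 ± 0.15 (adjusted p = 0.00202), although the Sox7 call ended with the mean of its probes. The tip cell gene Esm1 rose by 1.76 (adjusted p = 0.0052), and the general endothelial markers Pecam1 (−0.04) and Kdr (−0.08) did not change. With slide as a block the median was −0.33, and within slide 3 the mean difference was −0.50. The erythroid covariate moved the median to −0.21.

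Forebrain and midbrain progenitor genes fell by a median of 0.27, with 6 of 26 lower and 0 higher (adjusted p = 0.000152, and adjusted p = 0.412 with an estimated correlation). The forebrain factor Fezf1 fell by 0.95 ± 0.11 (adjusted p = 9.63e-05), Sox3 by 1.08 ± 0.15 (adjusted p = 0.000489) and Zic2 by 0.82 ± 0.13 (adjusted p = 0.00163), while Otx2 (0.04) did not change. Fitted with slide, the median was −0.42, and within slide 3 the mean difference was −0.58. With the erythroid covariate the median turned to 0.08.

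**Figure D3:**
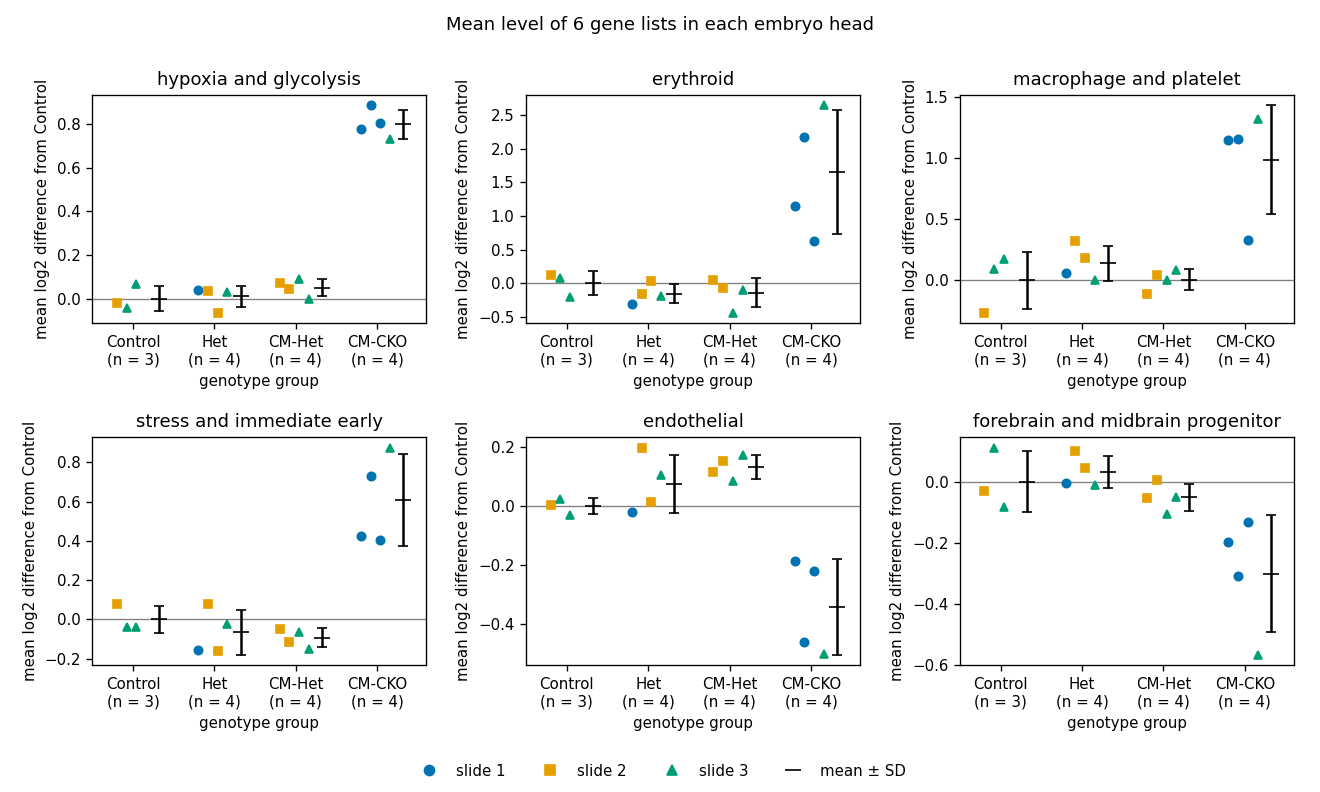
Mean log2 difference from the Control mean (vertical axis) over the genes of 6 lists in each embryo head, by genotype group, with point shape and colour for the slide and black bars for the group mean ± SD. The hypoxia and glycolysis score was 0.73 to 0.89 in CM-CKO heads and −0.07 to 0.09 in all others, whereas the erythroid score of CM-CKO heads ran from 0.63 to 2.64.

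Lists tied more closely to known TWIST1 functions held single changed genes but did not pass as lists. Of 18 mesenchyme and EMT transcription factors 2 fell and 0 rose, at a median of −0.17 (adjusted p = 0.0951), and with slide as a block this list passed (median −0.34, adjusted p = 0.00181), whereas with the erythroid covariate its median turned to 0.06. Mesenchyme markers (median −0.27, adjusted p = 0.215) were split. The smooth muscle actin Acta2 rose by 1.13 ± 0.18 (adjusted p = 0.00196), and Igf1 fell by 0.75 ± 0.17 (adjusted p = 0.0131), a call that ended with median scaling. In the extracellular matrix list, with a median of −0.06 (adjusted p = 0.505), Col6a1 fell by 0.96 ± 0.16 (adjusted p = 0.00232). Among integrins and adhesion receptors (median 0.02, adjusted p = 0.505) Itga3 rose by 0.63 ± 0.11 (adjusted p = 0.0028). Of the suture and craniosynostosis genes 3 fell and 0 rose (median −0.12, adjusted p = 0.106), among them Efna4, which fell by 0.59 ± 0.11 (adjusted p = 0.00473) and is also the only changed member of the ephrin and semaphorin guidance list (median −0.08, adjusted p = 0.274). Blocking by slide, both passed (adjusted p = 0.0268 and 0.00181), but with the erythroid covariate their medians turned to 0.06 and 0.20.

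Among mesoderm derivatives, head muscle mesoderm genes showed a median of 0.01, a mean of −0.03 and a test direction that was down (adjusted p = 0.845). Lhx2 fell by 0.91 ± 0.14 (adjusted p = 0.000923) and the pharyngeal regulator Tbx1 rose by 0.80 ± 0.15 (adjusted p = 0.00438). In the cardiac list 2 of 10 rose, with a median of −0.03 but a mean of 0.27 (adjusted p = 0.215), because the cardiac actin gene Actc1 rose by 2.26 ± 0.16 (adjusted p = 5.82e-07) while the heart genes Nkx2-5 (−0.20) and Ttn (−0.05) did not change. The slide-blocked Actc1 change was 2.31, and within slide 3 at 2.48. The trunk Hox and somite list, a marker of trunk tissue, had 0 of 7 changed (median 0.18, adjusted p = 0.215), with Tbx6 at 0.33 and Uncx at 0.43 not passing.

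Epithelial genes had a median of 0.08 (adjusted p = 0.106), and Krt19 rose by 1.08 ± 0.19 (adjusted p = 0.0026). The neural crest and arch list had a median of 0.01 (adjusted p = 0.845), and its 2 risen genes, Sox10 (0.72 ± 0.17, adjusted p = 0.0201) and Edn1 (0.61 ± 0.17, adjusted p = 0.0393), lost their call with slide as a block. Among neuron differentiation genes (median −0.14, adjusted p = 0.106) Tagln3 fell by 0.65 ± 0.16 (adjusted p = 0.0261), which also ended with slide as a block. In the ear and lens placode list (median −0.06, adjusted p = 0.705) Eya1 fell by 0.54 ± 0.14 (adjusted p = 0.0321), a call that ended with median scaling. Hindbrain Hox (median −0.05, adjusted p = 0.785), pharyngeal endoderm and ectoderm (median −0.00, adjusted p = 0.845) and notochord and floor plate genes (median 0.02, adjusted p = 0.842) held 0 changed genes.

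Signalling targets moved as single genes. Among FGF targets (median 0.16, adjusted p = 0.192) only Egr1 rose. In the BMP and TGF-beta list (median −0.11, adjusted p = 0.533) 2 rose and 3 fell: Id2 fell by 1.04 ± 0.17 (adjusted p = 0.0022), a call that ended with the mean of its probes, and Ccn2 rose by 0.96 ± 0.20 (adjusted p = 0.0107), which ended with slide as a block. Wnt targets (median −0.06, adjusted p = 0.44) had 3 lower genes, among them Sfrp1, which fell by 0.55 ± 0.12 (adjusted p = 0.0126) and lost its call with slide as a block. The Notch list (median −0.13, adjusted p = 0.528) had only Dll1 lower, by 0.41 ± 0.11 (adjusted p = 0.0307), and the hedgehog list (median −0.08, adjusted p = 0.505) only Cdon higher, by 0.37 ± 0.10 (adjusted p = 0.0415); both calls ended with slide as a block. Retinoic acid genes had 0 of 15 changed (median −0.08, adjusted p = 0.505). Of the sex-linked list 4 genes were measured, too few for a test, and Kdm5d (0.40) and Eif2s3y (0.64) did not differ between the groups.

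The second comparison held the germline Twist1 genotype constant, floxed over deleted, and asked what Mesp1-Cre, meant to remove the floxed copy in its lineage, changed (CM-CKO, n = 4, against Het, n = 4). The groups also differ in that the Cre allele replaces 1 copy of Mesp1. Chac1 rose by 3.37 ± 0.22 (SE) or 10.3-fold (adjusted p = 2.93e-07) and Trib3 by 3.02 ± 0.35 (adjusted p = 7.68e-05). Gja4 fell by 1.77 ± 0.16 (adjusted p = 4.11e-06), Klf2 by 1.73 ± 0.15 (adjusted p = 4.05e-06) and Aplnr by 1.59 ± 0.16 (adjusted p = 1.51e-05). Lum fell by 1.28 ± 0.09 (adjusted p = 6.97e-07), while Tagln rose by 1.49 ± 0.12 (adjusted p = 9.08e-07) and Actc1 by 2.27 ± 0.15 (adjusted p = 2.93e-07).

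In total 985 genes changed, 482 higher and 503 lower, with 185 higher and 20 lower by at least 2-fold and a median size of 0.59. A slide block gave 1172 genes, the replicate block with slide 681 and the erythroid covariate 50. Within slide 1, 982 of the 985 kept their sign, and within slide 3, 979 did, although those arrays had also served for the calls. The count was 639 without Het 2, 629 without Het 3 and 504 without CM-CKO 2, and a fit of only these 8 arrays gave 333 genes. Median scaling gave 582 genes.

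Red blood cell genes were again among the largest rises: Alas2 at 3.23 ± 0.46 (adjusted p = 0.000563), Kel at 3.14 ± 0.45 (adjusted p = 0.00055), Slc38a5 at 2.97 ± 0.47 (adjusted p = 0.00137), Slc4a1 at 2.88 ± 0.35 (adjusted p = 0.00013) and Sptb at 2.87 ± 0.38 (adjusted p = 0.000312). The phagocyte oxidase gene Ncf4 rose by 3.11 ± 0.47 (adjusted p = 0.00088) and the transcription cofactor Cited4 by 2.91 ± 0.45 (adjusted p = 0.00109). Of the erythroid list 17 of 21 rose (median 2.24, adjusted p = 1.7e-19, and adjusted p = 0.158 with an estimated correlation). In the macrophage and hematopoietic list 5 of 11 rose, among them Pf4 at 2.76 ± 0.39 (adjusted p = 0.00055), with a median of 0.51 (adjusted p = 5.24e-05, and adjusted p = 0.334 with an estimated correlation). Blocking by slide gave medians of 2.61 and 0.56. Mean differences for red blood cell genes were 1.63 within slide 1 and 2.83 within slide 3, and for macrophage and hematopoietic genes 0.82 and 1.32. The median of macrophage and hematopoietic genes turned to −0.04 with the erythroid covariate. Hspa1a, below background in Het, was at least 6.74-fold higher (adjusted p = 0.0322), a call that ended without background correction. With the erythroid covariate its fitted difference was −1.24 and did not pass.

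Hypoxia and glycolysis genes rose by a median of 0.71, with 24 of 31 higher and 0 lower (adjusted p = 6.1e-31, and adjusted p = 0.000144 with an estimated correlation). Ddit4 rose by 2.18 ± 0.15 (adjusted p = 4.98e-07), Stc2 by 1.95 ± 0.16 (adjusted p = 1.27e-06), Ankrd37 by 1.62 ± 0.14 (adjusted p = 2.64e-06) and P4ha2 by 0.96 ± 0.10 (adjusted p = 1.51e-05). With slide as a block the list median was 0.70, and the mean difference was 0.78 within slide 1 and 0.70 within slide 3. Stress and immediate early genes rose by a median of 0.44, with 12 of 24 higher (adjusted p = 1.01e-09, and adjusted p = 0.0214 with an estimated correlation), led by Ier3 at 2.34 ± 0.18 (adjusted p = 9.08e-07) and Egr1 at 1.59 ± 0.18 (adjusted p = 5.05e-05). The stress list stood at 0.58 with slide as a block, 0.68 within slide 1, 0.90 within slide 3 and 0.14 with the erythroid covariate.

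Endothelial genes fell by a median of 0.38, with 15 of 29 lower and 1 higher (adjusted p = 3.96e-08, and adjusted p = 0.158 with an estimated correlation). Gja5 fell by 1.30 ± 0.15 (adjusted p = 5.7e-05) and Emcn by 0.77 ± 0.12 (adjusted p = 0.00139). With slide as a block the median was −0.41, and the mean difference was −0.27 within slide 1 and −0.61 within slide 3. The median moved to −0.22 with the erythroid covariate. Forebrain and midbrain progenitor genes fell by a median of 0.36 (5 of 26 lower, adjusted p = 7.9e-05, and adjusted p = 0.395 with an estimated correlation), with Fezf1 lower by 0.88 and the eye field gene Rax at −0.88 ± 0.21 (adjusted p = 0.0149). Their block median was −0.39, and the differences were −0.21 within slide 1 and −0.56 within slide 3, but with the erythroid covariate the median turned to 0.07. The remaining large falls were Cygb (−1.45, adjusted p = 5.77e-06), Txnip (−1.31, adjusted p = 0.000563), Mogat2 (−1.19, adjusted p = 1.61e-05), Psmb1 (−1.16, adjusted p = 0.00746, ended in the fit of only these arrays) and Fam162b, which was below background in CM-CKO heads and at least 2.19-fold lower. With the erythroid covariate Psmb1 stood at 0.14 and did not pass.

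A further 6 lists passed by smaller margins. Extracellular matrix genes fell by a median of 0.14 (7 of 44 lower and 1 higher, adjusted p = 0.0365, and adjusted p = 0.590 with an estimated correlation), with Col15a1 at −0.89 ± 0.16 (adjusted p = 0.00393). Mesenchyme and EMT transcription factors fell by a median of 0.16 (3 of 18 lower, adjusted p = 0.0399, and adjusted p = 0.590 with an estimated correlation), with the skeletal patterning gene Alx4 at −0.87 ± 0.19 (adjusted p = 0.0109, ended in the fit of only these arrays). Ephrin and semaphorin guidance genes fell by a median of 0.15 (4 of 30 lower, adjusted p = 0.0175, and adjusted p = 0.590 with an estimated correlation), among them Epha5 at −0.64 ± 0.15 (adjusted p = 0.0142). Neuron differentiation genes fell by a median of 0.22 (2 of 25 lower, adjusted p = 0.0273, and adjusted p = 0.613 with an estimated correlation). Cardiac genes rose by a median of 0.06 (3 of 10 higher, adjusted p = 0.0399, and adjusted p = 0.401 with an estimated correlation), again through Actc1. Epithelial genes rose by a median of 0.07 (3 of 26 higher, adjusted p = 0.0428, and adjusted p = 0.590 with an estimated correlation), with Krt19 at 1.03 ± 0.17 (adjusted p = 0.00189), but the median was −0.01 with median scaling. The slide-block medians, in the same order, were −0.15, −0.31, −0.27, −0.25, 0.03 and 0.09, and the neuron differentiation (adjusted p = 0.0528) and cardiac (adjusted p = 0.156) calls ended. Within slide 1 the mean differences were −0.08, −0.18, −0.13, 0.03, 0.38 and 0.20, and within slide 3 they were −0.34, −0.46, −0.38, −0.55, 0.11 and 0.22. With the erythroid covariate the medians were 0.08, 0.02, 0.26, −0.08, 0.50 and 0.34. The first 3 of these had the opposite sign, but no list test was run with that covariate. Without CM-CKO 4 only 7 of the 12 lists passed, and each of these 6 calls ended when 1 or another single array was left out. The mesenchyme and EMT factor call also ended in the authors' value table (adjusted p = 0.0793), without background correction (adjusted p = 0.0560) and without Het 1, Het 4 or CM-CKO 2.

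Mesenchyme markers did not pass as a list (adjusted p = 0.223), yet 6 fell and 2 rose: the pericyte receptor Pdgfrb fell by 0.88 ± 0.17 (adjusted p = 0.00534), the chemokine Cxcl12 by 0.53 ± 0.10 (adjusted p = 0.00404), and Acta2 rose by 1.43 ± 0.17 (adjusted p = 0.000114).

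The third comparison was made within Cre carriers and set the deleted allele against the wild-type allele beside the floxed one (CM-CKO, n = 4, against CM-Het, n = 4). Pf4 rose by 3.80 ± 0.39 (SE) or 13.9-fold (adjusted p = 2.92e-05), Chac1 by 3.24 ± 0.22 (adjusted p = 3.24e-07) and Bhlhe40 by 3.01 ± 0.21 (adjusted p = 5.68e-07). Gja4 fell by 1.76 ± 0.16 (adjusted p = 4.9e-06), Aplnr by 1.38 ± 0.16 (adjusted p = 8.78e-05) and Lum by 1.31 ± 0.09 (adjusted p = 5.9e-07), and Klf2 was 2.82-fold lower (adjusted p = 2.43e-05).

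Here 1152 genes changed, 615 higher and 537 lower (192 and 18 by at least 2-fold, median size 0.58). A slide block gave 1071 genes, the replicate block with slide 399 and the erythroid covariate 132. Within slide 3, 1147 of the 1152 kept their sign, although those arrays had also served for the calls. Median scaling gave 887 genes, of which 38.9% were higher against 53.4% of the 1152, and moved the median of all genes to −0.12. The count was 677, 684, 751 and 730 without CM-Het 1 to 4 and 550 without CM-CKO 2.

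The other large rises were Alas2 (3.20 ± 0.46, adjusted p = 0.00062), Slc38a5 (3.11 ± 0.47, adjusted p = 0.000885), Ncf4 (3.07 ± 0.47, adjusted p = 0.000929), Kel (3.04 ± 0.45, adjusted p = 0.000716), Slc4a1 (3.03 ± 0.35, adjusted p = 9.43e-05), the erythrocyte actin-capping gene Tmod1 (2.91 ± 0.46, adjusted p = 0.00122) and Uba7 (2.88 ± 0.41, adjusted p = 0.000547). Endothelial nitric oxide synthase, Nos3, fell by 1.12 ± 0.16 (adjusted p = 0.000547), Gja5 by 1.26 ± 0.15 (adjusted p = 9.04e-05) and Txnip by 1.22 ± 0.19 (adjusted p = 0.000984). Psmb1 fell by 1.25 ± 0.24 (adjusted p = 0.00469) but stood at 0.047 with the erythroid covariate, where it did not pass. Fam162b, below background in CM-CKO heads, was at least 1.98-fold lower. Rapgef6 fell by 1.27 ± 0.25 (adjusted p = 0.00587) by its brightest probe, but only 2 of its 4 probes pointed that way and in the authors' value table it stood at 0.15.

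Of the 7 lists that passed, hypoxia and glycolysis (median 0.75, 23 of 31 higher, adjusted p = 1.72e-26, and adjusted p = 0.000303 with an estimated correlation) and stress and immediate early genes (median 0.63, 12 of 24 higher, adjusted p = 7.72e-10, and adjusted p = 0.0215 with an estimated correlation) also passed with an estimated correlation. Erythroid genes rose by a median of 1.87 (18 of 21 higher, adjusted p = 9.15e-18, and adjusted p = 0.158 with an estimated correlation) and macrophage and hematopoietic genes by 0.42 (6 of 11 higher, adjusted p = 2.26e-05, and adjusted p = 0.240 with an estimated correlation). Endothelial genes fell by a median of 0.49 (15 of 29 lower and 2 higher, adjusted p = 5.97e-11, and adjusted p = 0.0747 with an estimated correlation) and forebrain and midbrain progenitor genes by 0.23 (6 of 26 lower, adjusted p = 0.00222, and adjusted p = 0.539 with an estimated correlation). Hindbrain Hox genes were higher by a median of 0.10 (adjusted p = 0.0494, and adjusted p = 0.535 with an estimated correlation), with Hoxb2 at 1.53 (adjusted p = 0.0124) the only changed gene of 9, and this call ended with slide as a block (adjusted p = 0.442), in the authors' value table (adjusted p = 0.0562), without background correction (adjusted p = 0.0620) and without any 1 of CM-CKO 1 or 3, CM-Het 1, 2 or 4, Het 1 or 2 or Control 1 (adjusted p = 0.0505 to 0.183). The hindbrain Hox score averaged −0.53 in CM-Het heads (−0.64 to −0.42) and −0.06 in CM-CKO heads (−0.49 to 0.25). The difference thus lay in low CM-Het heads, not in a rise of CM-CKO over Control. The forebrain and midbrain call ended without CM-CKO 4 (adjusted p = 0.0711), and its median turned to 0.09 with the erythroid covariate. The block medians, in the order in which the lists are given, were 0.67, 0.72, 2.69, 0.47, −0.44, −0.30 and 0.14, and the mean differences within slide 3 were 0.69, 0.98, 2.92, 1.27, −0.63, −0.49 and 0.05. With the erythroid covariate the endothelial median was −0.28, the stress median 0.23 and the hypoxia median 0.62. The slide block also brought the mesenchyme and EMT factor (adjusted p = 0.0121), suture and craniosynostosis (adjusted p = 0.0257), ephrin and semaphorin guidance (adjusted p = 0.00136) and p53 and apoptosis lists (adjusted p = 0.0412) past the threshold. The first 3 of these had medians of 0.08, 0.12 and 0.24 with the erythroid covariate, of the opposite sign but not tested.

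Het against Control (n = 4 and n = 3) asked what loss of 1 Twist1 copy in all cells changes without Cre. By limma 0 of 11625 genes passed, with 636 at an unadjusted p under 0.05, against 581.25 that chance alone would give. Twist1 itself had the smallest adjusted p (−0.95 ± 0.15 SE, adjusted p = 0.111) and was the only gene to pass with array weights, with trended and robust empirical Bayes, or without Het 4, while all other settings gave 0. The next values, none of which passed, were the glutathione transferase Gstm6 at −1.05, Atp2b4 at −0.52 and Pla2r1 at −0.55 (each with adjusted p = 0.24) and the collagen receptor Ddr2, which was below background in Control (adjusted p = 0.477). Of the lists 0 of 30 passed (smallest adjusted p = 0.357).

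CM-Het against Control (n = 4 and n = 3) asked what Mesp1-Cre changes on the floxed over wild-type genotype, where it is meant to remove 1 copy of Twist1 in the lineage and also replaces 1 copy of Mesp1. By limma 0 genes passed, with 413 at an unadjusted p under 0.05. Other settings gave 0 to 7 genes. The mean of probes gave Mogat2 and Rsf1, the fit of only these arrays gave Prcp and Thumpd1, the erythroid covariate gave Hoxa2 and Hoxb2, and array weights gave Coa4, Hoxa2, Lrrc51, Mogat2, Prcp, Stard10 and Thumpd1, all named after their values were seen. The smallest p belonged to Lrrc51 (0.80 ± 0.13 SE, adjusted p = 0.246), Coa4 (−0.70 ± 0.13, adjusted p = 0.263), Mogat2 (−0.64 ± 0.13, adjusted p = 0.544), Prcp (0.91 ± 0.20, adjusted p = 0.658) and Thumpd1 (1.00 ± 0.22, adjusted p = 0.658), none of which passed. Median scaling moved the median of all genes to 0.13.

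Of the lists in CM-Het against Control 3 passed, each without a single changed gene and none with an estimated correlation. Hindbrain Hox genes were lower (median −0.15, mean −0.53, adjusted p = 1.61e-05, and adjusted p = 0.229 with an estimated correlation), with Hoxb2 at −1.58, Hoxb1 at −1.25 and Hoxa2 at −1.09. Neuron differentiation genes were lower (median −0.19, adjusted p = 4.22e-05, and adjusted p = 0.897 with an estimated correlation), which ended without Control 2 (adjusted p = 0.533). Endothelial genes were higher (median 0.12, adjusted p = 0.000834, and adjusted p = 0.897 with an estimated correlation). Slide-block medians were −0.13, −0.19 and 0.11. Within slide 2 the mean differences were −0.60, −0.04 and 0.13, and within slide 3 they were −0.49, −0.27 and 0.13. Without Control 3, 6 lists passed.

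Whether the effect of Mesp1-Cre depends on the other Twist1 allele was tested by the interaction (n = 3 to 4 per group). The vessel genes Gja4 (−2.004 ± 0.23 SE, adjusted p = 0.00029), Aplnr (−1.49 ± 0.23, adjusted p = 0.00454), Klf2 (−1.46 ± 0.22, adjusted p = 0.00404) and Gja5 (−1.36 ± 0.21, adjusted p = 0.00475) had negative interactions, as did Txnip (−1.40 ± 0.28, adjusted p = 0.0224). With Cre on the wild-type allele the changes of these 5 genes ran from −0.27 to 0.23, and none passed. The red blood cell genes Alas2 (3.49 ± 0.68, adjusted p = 0.0224), Slc38a5 (3.37 ± 0.69, adjusted p = 0.0278), Tmod1 (3.25 ± 0.68, adjusted p = 0.0296) and Kel (3.23 ± 0.66, adjusted p = 0.0271), and Ncf4 (3.61 ± 0.69, adjusted p = 0.0209), had positive interactions, each of which ended with trended and robust empirical Bayes.

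In all 124 genes passed, 78 positive and 46 negative, with a median size of 1.12, and 263 passed with slide as a block, 87 with the replicate block and slide and 18 with the erythroid covariate. The count was 57 to 72 without any 1 of CM-Het 1, 2, 3 or 4, 60, 64 and 59 without Control 1, 2 and 3, 77 without Het 4, 61 without CM-CKO 2, 203 without Het 1, 199 without CM-CKO 1 and 330 without CM-CKO 3. Median scaling moved the median of all genes to −0.21. Among the lists, hypoxia and glycolysis (median 0.74, 10 of 31 genes positive, adjusted p = 0.000316 with an estimated correlation) and stress and immediate early genes (median 0.59, adjusted p = 0.0122 with an estimated correlation) passed in both tests. Erythroid (2.32, adjusted p = 0.159 with an estimated correlation), endothelial (−0.52, adjusted p = 0.0620 with an estimated correlation), macrophage and hematopoietic (0.42), cardiac (0.13), ephrin and semaphorin guidance (−0.20), extracellular matrix (−0.18) and forebrain and midbrain progenitor genes (−0.24) passed only with the preset correlation, and the cardiac call ended with slide as a block. It also ended without any 1 of CM-Het 2, Het 1, Het 2, Control 1, Control 3 or CM-CKO 3 (camera adjusted p = 0.0510 to 0.234). The ephrin and semaphorin call ended in the authors' value table (camera adjusted p = 0.0812) and without Het 1 (0.0713). The extracellular matrix call ended without Het 2 (camera adjusted p = 0.0510) or Control 3 (0.0581). Without CM-CKO 4 the extracellular matrix (adjusted p = 0.0773), forebrain and midbrain (adjusted p = 0.0654) and ephrin and semaphorin (adjusted p = 0.362) interaction calls ended, and with the erythroid covariate their medians turned to 0.06, 0.13 and 0.26, while the endothelial median was −0.36.

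The Cre effects on the 2 Twist1 genotypes, which share no arrays, were not correlated across genes (Pearson r = −0.027, Spearman −0.026), and 485 of the 985 genes changed in CM-CKO against Het had the same sign in CM-Het against Control (49.2%). The effects of the deleted allele with and without Cre had r = 0.071 (Spearman 0.101), with the same sign for 641 of 1152 changed genes (55.6%), and r = 0.231 with slide as a block. In both pairs the second comparison, with Control, held 0 changed genes. There the genes changed in the first had a median size of 0.10, against a median SE of 0.14 over all genes. Values so near their error correlate weakly even where small effects are shared, so the correlations cannot exclude a small shared effect. In the first comparisons the same genes had median sizes of 0.594 and 0.575, although they were chosen there for passing. Effects of equal size would have given larger values in the second comparisons. For these genes as a set the sizes thus argue against equal effects.

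No excess of changed genes near the targeted loci passed. Within 10 Mb of Twist1 lay 5 genes changed against Control (0.60% of changed genes), 7 against Het (0.71%) and 6 against CM-Het (0.52%), against 0.38% of all genes. Within 10 Mb of Mesp1 lay 6 (0.71%), 8 (0.81%) and 5 (0.43%), against 0.59% (Fisher's exact test, adjusted p = 1 in each case). The smallest unadjusted p by Fisher's exact test was 0.0954, near Twist1 against Het. With 44 and 69 genes in these windows, a small excess could be missed.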

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

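Of the tests in this part, those of heart and trunk tissue, of slide and array signal by the erythroid score and of slide in the interaction splits were chosen after the results were seen, and the conditions on the red blood cell test and the heart and trunk test were tightened after their values were seen.

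The hypoxia and glycolysis genes stood higher in every CM-CKO head (scores 0.73 to 0.89) than in any other head (−0.07 to 0.09). Slide is an unlikely cause, since the median change of the 24 called members against Het, with slide as a block, was 0.976 of the value without it. With the erythroid list mean as a covariate the ratio was 0.846, and the score difference was 0.83 (95% bounds 0.674 to 0.989) against 0.79 without it. Only 8 of the 24 genes still passed, while their median change went from 0.879 to 0.744 and their median SE from 0.128 to 0.229. The erythroid score did not overlap between CM-CKO heads (0.63 and above) and all others (0.126 and below). The adjustment thus rests mainly on a straight line through the CM-CKO heads and cannot fix the share due to blood. Among those heads the hypoxia score stayed at 0.73 to 0.89 while the erythroid score ran from 0.63 to 2.64, which argues against blood as the main source. Heart or trunk tissue left on the heads stays open. The larger of the cardiac and trunk list medians against Het was 0.153, that of the trunk list, but members of both lists went both ways, which decides nothing. Of the trunk genes 5 of 7 were higher (all 7 from −0.04 to 0.30), with CM-CKO scores of 0.0744 to 0.283 against −0.0991 to 0.156 in other heads. Of the cardiac genes 6 of 10 were higher and 4 lower, and Actc1 rose by 2.27. All 4 CM-CKO cardiac scores (0.102 to 0.622) lay above those of all other heads (−0.159 to 0.0951), but without Actc1 only CM-CKO 3 did (0.410, the other CM-CKO heads −0.115 to −0.0127, all other heads −0.166 to 0.0867), and Nkx2-5 (0.01) and Ttn (−0.10) did not change. Most cardiac genes lay near background, which limits what they exclude. A response of the heads to low oxygen, possibly following poor vessel function, also stays open, since oxygen was not measured. The fixed lists were also meant to mark RNA handling stress. The stress and immediate early score was 0.40 to 0.88 in CM-CKO heads and −0.16 to 0.08 in all others. Whether the handling of the heads differed between groups was not tested.

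By the erythroid score the CM-CKO heads differed more among themselves than the heads of any other group, running from 0.63 to 2.64. This did not hold for every list, since the cell cycle score had its smallest SD in CM-CKO heads (0.013). By the hypoxia score the 3 heads on slide 1 ranged 1.01 times as widely as the widest other group. This cannot decide whether slide bears on that score, since there was little excess spread to explain (SD 0.065 in CM-CKO heads, 0.039 to 0.058 in the other groups). By the erythroid score the same ratio was 3.13, so a slide effect is unlikely to account for the spread in blood genes. Array signal had a Spearman rho of −0.4 with the hypoxia score over 4 arrays, too few to judge, and the highest erythroid score among 11 arrays of other groups with signal in the same range or above was 0.126. Variable bleeding at dissection and variable severity of the phenotype could each give such a spread, and no test here separates them. The unchanged Hbb-bh1 and Hbb-y do not, since they lay near the top of the scale (13.67 and 13.68 in Control, highest of any gene 14.05), while the beta globins Hbb-bs and Hbb-bt, chosen after their values were seen, rose by 2.30 and 2.33 from 9.55 and 9.63.

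Random regrouping of the arrays was used to ask whether the counts of changed genes could arise by chance. Only 1 of 35 splits, the real one, reached the counts of CM-CKO against Control (841, highest other split 598), against Het (985, highest other 358) and against CM-Het (1152, highest other 1). The highest other split against Het was the 1 that followed slide 1. For Het against Control and CM-Het against Control the real count was 0, which all 35 of 35 splits reach by construction, so these splits test nothing (highest other 2 and 1). For lists, chance was not excluded: 19 of 35 splits called at least the 6 lists of CM-CKO against Control (highest other 21), 6 of 35 at least the 12 against Het (highest other 24) and 19 of 35 at least the 7 against CM-Het (highest other 20). For the interaction 2 of 100 splits reached 124 genes, and the highest other gave 461, several times the real count, which points to a structure of the samples. In that split all 4 CM-CKO heads and all 4 arrays of slide 1 had labels that count with the same sign, and with slide as a block it gave 0 genes, where the real split gave 263. Of the 7 splits with all CM-CKO heads on the same side 5 gave 0 genes.

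The effect of Cre differed between the Twist1 genotypes for 124 genes. Among those named were Ncf4 (3.61), Alas2 (3.49), Slc38a5 (3.37), Tmod1 (3.25), Kel (3.23), Gja4 (−2.004), Aplnr (−1.49), Klf2 (−1.46), Txnip (−1.40) and Gja5 (−1.36), with 28 other named genes. The lists that differed had medians of 2.32 (erythroid), 0.74 (hypoxia and glycolysis), 0.59 (stress and immediate early), 0.42 (macrophage and hematopoietic), 0.13 (cardiac), −0.52 (endothelial), −0.24 (forebrain and midbrain progenitor), −0.20 (ephrin and semaphorin guidance) and −0.18 (extracellular matrix). With an estimated correlation only the hypoxia and stress lists still passed.

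A single array lay far from the other 3 of its group in 24 of 507 sets examined, where 25.35 would be so by chance. Among list scores these were mesenchyme and EMT factors in Het 1 (0.087), cardiac genes in CM-CKO 3 (0.622), neuron differentiation in CM-Het 2 (−0.00011), ear and lens placode in CM-CKO 2 (−0.192) and hypoxia and glycolysis in Het 3 (−0.065). Among gene levels on the log2 scale, CM-CKO heads stood apart in Pf4 (7.46) and Treml1 (5.36) in CM-CKO 3, P4ha2 (8.72) and the Y-linked Eif2s3y (4.37) in CM-CKO 2, Pdgfrb (6.69) in CM-CKO 1 and Itga3 (8.55) in CM-CKO 4. Het heads did so in Eif2s3y (4.21), Ets1 (10.44), Gstm6 (4.93) and Spon1 (4.29) in Het 4, Klf2 (7.47) in Het 2 and Slc38a5 (6.47) in Het 1. In CM-Het heads the genes were Foxa2 (5.72), Itga3 (8.08), Sesn2 (5.88) and Tbx6 (5.27) in CM-Het 1, Nos3 (7.53) in CM-Het 2, and Acta2 (10.57) and Vcl (10.42) in CM-Het 3.

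Probes without a gene name also changed. Of 3235 such probes 110 changed in CM-CKO against Control (64 higher), 123 against Het (68 higher) and 165 against CM-Het (91 higher), 1 in CM-Het against Control and 33 in the interaction.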

How the results depend on the processing

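Of the alternatives in this part, the Xist and erythroid covariates were chosen after the results were seen. Of 230 results for named genes 187 passed, and 73 of these kept their direction and their call under every alternative fixed beforehand. The Xist covariate, the random slide block, both other detection filters, trended and robust empirical Bayes, the authors' value table and fits without background correction left the counts for CM-CKO within 1.5 times. Signal over background limits dim genes, and changes of genes below background are given in the comparisons only as lower limits. Their values below, as for Hspa1a, are fitted differences that carry no sure direction. The cause was not tested for any change below, unless stated.

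For CM-CKO against Control (841 genes) median scaling gave 434, array weights 1321, the erythroid covariate 166, only these arrays 272, and leaving out 1 array 385 to 1029. Against Het (985) median scaling gave 582, the erythroid covariate 50, only these arrays 333, and leaving out 1 array 504 to 1272. Against CM-Het (1152) the erythroid covariate gave 132 and leaving out 1 array 550 to 1256. Het against Control (0) gave 1 with array weights, 1 with trended and robust empirical Bayes and 0 to 1 leaving out 1 array. CM-Het against Control (0) gave 2 with the mean of probes, 7 with array weights, 2 with the erythroid covariate and 2 with only these arrays. The interaction (124) gave 263 with slide as a block, 294 with array weights, 18 with the erythroid covariate and 57 to 330 leaving out 1 array, and it needs all 4 groups, so no fit of fewer groups was made. Fewer arrays in a fit leave fewer degrees of freedom. A fit of only CM-CKO and the group compared also drops groups that varied less than CM-CKO heads by the erythroid score. The erythroid score separates CM-CKO heads (0.63 and above) from all others (0.126 and below), so its covariate takes up part of the genotype difference. Red blood cell genes such as Kel kept little of their change. For the 24 hypoxia genes called against Het the median change went from 0.879 to 0.744 and the median SE from 0.128 to 0.229.

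The replicate numbers were not taken to pair the arrays, since only 5 of 21 same-numbered pairs correlated above 0.1 (mean 0.041) and nothing in the labels ties them, although 9 of 15 arrays correlated best with their own number, a hint of shared factors. With the replicate block the counts were 755, 983, 1129, 0, 0 and 153. The replicate block together with slide gave 31 against Control, 681 against Het and 399 against CM-Het, and a Twist1 change of −0.32. The replicate block without slide gave 5 lists in CM-Het against Control and correlations of −0.112 between the Cre effects and 0.0136 between the deleted allele effects.

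The Twist1 change of −0.76 against Control was −0.51 with slide as a block and −0.78 with the erythroid covariate, where it did not pass. The lists called with an estimated correlation were 1, 2 and 2 for CM-CKO against Control, Het and CM-Het, 0 for CM-Het against Control and 2 for the interaction. Leaving out 1 array gave 7 to 12 lists against Het and 3 to 6 in CM-Het against Control. The correlation of the Cre effects was −0.051 with slide as a block and −0.052 to 0.014 leaving out 1 array, and that of the deleted allele effects was 0.231 and 0.0048 to 0.149. Nearness to Twist1 and Mesp1 gave 0 tests passing at 5, 10 and 20 Mb. Those of Het and CM-Het against Control, with 0 changed genes, could not pass.

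With the erythroid covariate the direction turned for Hspa1a (−0.74 against Control, −1.24 against Het), Psmb1 (0.14 against Het, 0.047 against CM-Het), Gp9 (−0.088), Lmx1a (−0.44), Ddit4l (0.092) and Ddit3 (−0.018) against Het, none of which passed, and a further 133 of the 187 passing results no longer passed. In the authors' value table Rapgef6 against CM-Het turned to 0.15. With slide as a block 34 of the 187 no longer passed, and with the replicate block and slide 96 did not. The endothelial medians with the erythroid covariate were −0.21, −0.22 and −0.28 for CM-CKO against Control, Het and CM-Het and −0.36 in the interaction. Among called lists the erythroid covariate changed the sign of the median, without a list test, for forebrain and midbrain genes in all 3 CM-CKO comparisons (0.07 to 0.09) and in the interaction (0.13), for extracellular matrix, EMT factor and ephrin and semaphorin genes against Het (0.08, 0.02 and 0.26), for the first and last of these in the interaction (0.06 and 0.26) and for macrophage and hematopoietic genes against Het (−0.04). The erythroid list itself, whose mean is the covariate, went to −0.04 against Control and −0.03 against Het.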

Other observations

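The tests of strain sequence and of slide for genes near Mesp1 in this part were chosen after the result was seen.

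Further members of the hypoxia list, chosen after their values were seen, were higher in CM-CKO heads. Against Control the aldolase Aldoc stood at 0.89 (adjusted p = 0.00049), the pyruvate dehydrogenase kinase Pdk1 at 1.36 (adjusted p = 7.59e-05), the oxygen sensor Egln3 at 1.32 (adjusted p = 0.000107), the glucose transporter Slc2a1 at 0.72 (adjusted p = 0.00092) and the carbonic anhydrase Car9 at 0.66 (adjusted p = 0.0016), while Gapdh and Ldha (each −0.05) did not change. Of genes linked to amino acid shortage or unfolded protein, for which no list was fixed, Ddit3 stood at 1.25 (adjusted p = 0.033) beside Chac1 and Trib3. With the erythroid covariate Trib3 against Control was 1.30 and no longer passed (adjusted p = 0.0639), and Ddit3 against Het turned to −0.018.

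Erythroid scores in the CM-CKO heads stood in the order CM-CKO 3, 1, 2 and 4, and the endothelial score ran from −0.50 to −0.19 in these heads against −0.03 to 0.20 in all others. Of further erythroid list members, chosen after their values were seen, Nfe2 (2.56, adjusted p = 0.0046), Hemgn (2.49, adjusted p = 0.0094) and Epor (2.02, adjusted p = 0.024) rose, while the globins Hba-a1 (0.41), Hba-x (0.22) and Hbb-b2 (0.73) did not pass against Control. Hba-a1 and Hba-x lay near the top of the scale in Control (13.51 and 13.52) and Hbb-b2 near background (4.69), so no difference between globins and other members was tested.

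Genes near Mesp1, the site of the Cre allele, were frequent among the smallest p-values of CM-Het against Control. Of the 50 genes with the smallest p, 5 (10%) lay within 20 Mb of Mesp1, against 1.16% of 11610 genes with a position (Fisher's exact p = 0.000275, odds ratio 9.76, 95% interval 2.98 to 25.1), and all 5 had the same sign in CM-CKO against Het. The excess was not confined to that window, which was chosen after the result was seen: 15 of the 50 lay on chromosome 7 (Fisher's exact p = 4.68e-06), among them Lrrc51 and Coa4, with the smallest p of all, at 22.1 and 20.7 Mb, and others from −60.5 to 60.3 Mb from Mesp1. Sequence of another strain linked to the Cre allele is consistent with this result, and Mogat2, whose log2 difference with Cre was −0.64 on the wild-type background and −1.19 on the deleted background, could carry such a part in its changes. Slide is an unlikely cause, since with slide as a block 4 of the 50 still lay there (Fisher's exact p = 0.00266). Strain variants under a probe were not examined, and no gene of CM-Het against Control passed by itself.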
